A study of Homo sapiens with 54 samples.

How the data were processed

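Expression was measured in 54 arrays of 9 established human cell lines, 2 arrays for each line at 0, 8 and 36 h, on the Affymetrix Gene 1.0 ST platform. Per the labels' protocols, total RNA was extracted with an Exiqon kit and 100 ng was turned into biotinylated cDNA with the Affymetrix WT protocol. Per the submitters' processing notes, the authors made the values with Affymetrix Expression Console 1.0 and RMA, and the deposited values are on the log2 scale, with array medians of 4.98 to 5.31. Whether all arrays went through RMA together is not given in the sources used here. The calcitriol dose is not given in the sources used here. The series compares lymphoblastoid and ENCODE lines stimulated with calcitriol for 8 h or 36 h with untreated cells.

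Groups were taken from the cell line and time of each sample's labels. The titles of 1 line name another line than its cell line field, GM10854, and the field was used. Sample titles come in 2 styles, 1 for 6 lines and 1 for 3 (GM12878, AG09319 and HepG2), so title style and line cannot be told apart for a single line. The replicate labels give a number and nothing on how the cultures were kept, and arrays were not paired by it.

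The deposited table holds 33297 probe sets, of which 21214 are in the probe table used. The 19460 probe sets with exactly 1 gene symbol were kept, 1754 with several symbols and 12083 without a name were set aside, and 24 probe sets of XIST and Y-linked genes were left out, which left 19436 probe sets of 18394 symbols. Of the probe sets with 1 symbol 19429 matched a gene ID of the reference table, and 0 symbols needed an update. Genes are given by symbol, and genome positions were not used here. No filter on low values was applied in the main settings. No pair of arrays was identical (0).

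Tests used limma 3.58.1 in R 4.3.3 with its default moderation, two-sided, with Benjamini-Hochberg adjustment over the probe sets of a comparison and a threshold of 0.05. For statements over 9 lines, over the 4 lymphoblastoid lines or between the 4 lymphoblastoid and 5 other lines, the 2 arrays of a group were averaged and the line was the replicate, with time and line as terms (16 residual degrees of freedom for 9 lines). Single lines, and the pairs HL60 with K562 and AG09309 with AG09319, were tested in 1 fit of 27 groups to the 54 arrays (27 residual degrees of freedom, 8.88 prior degrees of freedom). Differences between lines were tested as differences of their changes. Depth has no counterpart on arrays, and the number of arrays limits the precision.

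Before the data were examined, 18 gene lists were fixed, with 403 entries of which 362 were measured. They were vitamin D response genes, vitamin D receptor and metabolism, B cell, MHC class II, NF-kB and inflammatory, interferon-stimulated, autoimmune disease loci, cell cycle, growth arrest and p53 targets, monocyte and macrophage, neutrophil granule and promyelocyte, erythroid, hepatocyte, fibroblast and extracellular matrix, immediate early and heat shock, unfolded protein and amino acid stress, hypoxia and glycolysis, and cholesterol synthesis. A gene on several probe sets was represented by the one with the highest mean. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 522 tests, and again with the correlation estimated from the residuals. Of the 522 tests 172 passed at the preset correlation and 44 with the estimated one. The comparisons, tests, alternatives and rule for naming genes were also fixed before the data were examined.

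Genes were named by rule. CYP24A1, VDR, CD14, CAMP, THBD, G0S2 and CDKN1A were followed in every line. For means over lines and for the class difference the 10 largest rises and 10 largest falls among calls could be named, over 9 lines only with at least 8 lines in the direction of the mean. For single lines and pairs these were 5 in each direction, for single lines only where both treated arrays lay outside the range of both 0 h arrays, and for each called list the 4 members with the largest change. Where nothing passed, the genes with the smallest p were given as not passing. Genes shared between lines, the levels of lymphoid and immediate early genes in AG09309, the genes of its comparison of 36 h with 8 h and the values of named genes in other lines were chosen after their values were seen.

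Overlaps between lines are given with the number expected of independent lists. The changes at 8 h and 36 h share 0 h arrays, so their overlap and covariance are given beside 20 simulations of unchanged groups with the same sharing. Relations with the VDR level used Pearson and Spearman coefficients with exact permutation over all pairings, for the 9 lines and, chosen after the data were seen, for the 6 lines of the first title style (scipy 1.17.1). Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R used the package data.table (version 1.17.8).

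The alternatives were quantile normalization, centring on array medians, a filter on dim probe sets, moderation with a trend and robust option, 1 probe set per gene, a minimum change of 0.58, arrays fitted one by one, only the arrays of the lines compared, array weights, the replicate number as a block, each title style alone and leaving out each array or line. Those chosen after seeing the data were leaving out the 3 arrays that stood apart (AG09319 8 h replicate 2, HepG2 0 h replicate 2 and K562 36 h replicate 1), leaving out small RNAs, and restricting AG09309 to probe sets lower in lymphoblastoid lines than in AG09319.

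The procedure was tested on simulated data with 200 changed probe sets in 5 simulations. For a single line it recovered 9.3%, 73.1% and 99.1% of changes of 0.5, 1 and 2 log2 units, with 7.8 false calls on average. Over 9 lines it recovered 91% of changes of 0.5 with 9.6 false calls, and over 4 lines 44.5% with 8.4. A list shifted by 0.5 was called in 5 of 5 simulations, and no other list was (0). The simulated noise was independent between genes and the preset correlation was used. False calls of lists whose genes vary together were therefore not tested. The noise of a probe set also had the same spread in every group, and the single line simulated was HL60 at 36 h. False calls in groups with a wider spread, such as those with an array that stood apart, were not tested either.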

Results

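Expression was measured on Affymetrix Gene 1.0 ST arrays in 9 human cell lines before calcitriol, the hormonal form of vitamin D, and after 8 h and 36 h with it. The 4 lymphoblastoid lines, B cells transformed with Epstein-Barr virus, were GM07019, GM07348, GM10854 and GM12878. The 5 others were the fibroblast lines AG09309 and AG09319, the promyelocytic leukaemia line HL60, the chronic myeloid leukaemia line K562 and the hepatoma line HepG2. K562 has erythroid features. Each line had 2 arrays at each time, 54 arrays in 27 groups. Array medians ran from 4.98 to 5.31 on the log2 scale, and the correlation between the 2 arrays of a group had a median of 0.987. It was lowest in AG09319 at 8 h (0.897), HepG2 at 0 h (0.954) and K562 at 36 h (0.970), and in each of these groups 1 array stood apart from the rest of its line. No detection calls were used, so for levels well below these medians it cannot be told whether a gene lay above background, and changes from or to such levels are not exact folds. Untreated cultures kept for 8 h or 36 h were not analysed here, so every change against 0 h belongs to calcitriol and to culture time together. A change is a log2 difference with its standard error after the ± sign, and for a single line it compares 2 arrays with 2. For single lines and pairs of lines that error comes from 1 spread per probe set shared by all 27 groups. It is therefore not the spread of that line itself, and neither is the p-value based on it. Over all probe sets the SD between the 2 arrays was largest in AG09319 at 8 h (0.539), HepG2 at 0 h (0.348) and K562 at 36 h (0.332). The number of arrays limits the precision, and the p-values measure only the spread between these samples.

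The first comparison asked which genes responded to calcitriol in all 9 lines. At 36 h CYP24A1, the enzyme that begins the breakdown of calcitriol, had the largest mean rise, 2.79 ± 0.49 (adjusted p = 0.00569), and was higher in 9 of 9 lines. VDR, the calcitriol receptor, rose by 0.44 ± 0.10 (adjusted p = 0.0354). EFL1, a ribosome maturation factor, rose by 0.81 ± 0.14 (adjusted p = 0.00509, 8 of 9 lines), and DDIT4, a stress-induced inhibitor of mTOR signalling, by 0.71 ± 0.12 (adjusted p = 0.00511, 8 of 9 lines). The protease inhibitor SERPINB1 (0.68 ± 0.11), the transcription factor HIVEP2 (0.60 ± 0.10) and the surface peptidase DPP4 (0.72 ± 0.14) were higher in 9 of 9 lines, and SERINC2 (0.62 ± 0.10) was higher in 8. The other rises named by the rule were the acyl-CoA synthetase ACSL1 (0.80 ± 0.17), the small RNA SNORD13P1 (0.75 ± 0.16) and DDX60L (0.59 ± 0.14), and the falls included MPLKIP (-0.32 ± 0.07) and WDR62 (-0.27 ± 0.06).

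Of 19436 probe sets tested, 92 changed at 36 h over the 9 lines, 88 higher and 4 lower. They covered 66 genes, since 26 of the probe sets belonged to the multicopy transcript LINC00965 and 2 to MPLKIP. Fewer genes than these 66 were called when 1 probe set per gene was tested. After quantile normalization 72 were higher and 23 lower. The count was 51 without GM07019, 47 without GM10854, 54 without K562, 45 without GM12878 and 155 without AG09319, and it was 69 without the 3 arrays that stood apart. Without those 3 arrays the ACSL1 mean was 0.72 (adjusted p = 0.0845). Leaving out 1 line took ACSL1, SNORD13P1, DPP4, DDX60L, MPLKIP and WDR62 to adjusted p-values of up to 0.117, 0.125, 0.0633, 0.141, 0.136 and 0.0971, and after quantile normalization SNORD13P1 and DDX60L had 0.0513 and 0.0679. The 6 lines of the first style of sample title gave 29 and the 3 lines of the second gave 0.

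At 8 h no probe set passed limma's test over the 9 lines (0 changed, 542 at an unadjusted p under 0.05 where chance gives 972). Among those leading the ranking were CYP19A1, the aromatase, at 0.37 ± 0.09 and the small RNA SNORD34 at -0.49 ± 0.11, both with an adjusted p of 1. The changes at 8 h and 36 h share their 0 h arrays. Across probe sets, which are not independent replicates, their correlation was 0.183 with a covariance of 0.00176, where simulated groups without any change gave 0.503 and 0.00293. With the 0 h arrays divided between the times the correlation was -0.39 and the covariance -0.00758. In the 6 lines without an array that stood apart these were 0.259 and 0.00366.

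The 9 lines were also compared between 8 h and 36 h. SCD, the stearoyl-CoA desaturase, rose by 0.60 ± 0.10 (adjusted p = 0.00258), and MSMO1, a sterol oxidase, by 0.64 ± 0.13 (adjusted p = 0.0259). SERPINB1 rose by 0.63 ± 0.11 (adjusted p = 0.00458) and the interferon-induced helicase DDX60 by 0.57 ± 0.11 (adjusted p = 0.0135). The small nucleolar RNAs SNORD115-44 (0.94 ± 0.17, adjusted p = 0.00441) and SNORD116-6 (0.72, adjusted p = 0.0116) also rose. The falls were DND1 (-0.41 ± 0.09), BTBD6 (-0.32 ± 0.06) and LINC02983 (-0.32). In all 72 probe sets changed, 69 higher and 3 lower (57 and 10 after quantile normalization), from 44 genes. Of the 72, 26 belonged to LINC00965. Fewer were called with 1 probe set per gene, and fewer still without small RNAs as well. In either title style alone, with fewer lines, none was called. Leaving out K562 gave 40, GM12878 43 and HL60 126, and leaving out the 3 arrays that stood apart gave 38, with MSMO1 at 0.42 (adjusted p = 0.0846) and SNORD116-6 at 0.50 (adjusted p = 0.377). Leaving out 1 line took MSMO1, DDX60, DND1, BTBD6 and LINC02983 to adjusted p-values of up to 0.12, 0.0503, 0.12, 0.0685 and 0.127.

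In the 9-line mean at 36 h several gene lists fixed in advance were called at the preset correlation, and none of those below with an estimated one. In the vitamin D response list 2 of 32 measured members rose, CYP24A1 and SERPINB1, and 30 did not pass; 6 rose when adjusted over the list alone. The list's adjusted p was 0.013, and adjusted p = 0.478 with an estimated correlation between genes. In the receptor and metabolism list CYP24A1 and VDR rose of 14 members (list adjusted p = 0.0473, 0.144 without the 3 arrays that stood apart, and adjusted p = 0.478 with an estimated correlation). None of 36 cell cycle genes passed on its own and 25 fell when adjusted over the list alone, with a list median of -0.31 (adjusted p = 8.11e-21, adjusted p = 0.336 with an estimated correlation). In cholesterol synthesis INSIG1 (0.55 ± 0.12) and CYP51A1 (0.36) rose of 13 members, 8 when adjusted over the list alone (adjusted p = 1.61e-07, adjusted p = 0.33 with an estimated correlation). DDIT4 rose among 19 genes of unfolded protein and amino acid stress, 11 when adjusted over the list alone (adjusted p = 7.8e-08, adjusted p = 0.243 with an estimated correlation). VEGFA, the angiogenic growth factor, rose by 0.41 ± 0.07 among 19 hypoxia and glycolysis genes, 5 when adjusted over the list alone (adjusted p = 0.359 with an estimated correlation). Between 8 h and 36 h 3 of 13 cholesterol genes rose, INSIG1 (0.54), CYP51A1 (0.43) and SQLE (0.38), and 10 when adjusted over the list alone (adjusted p = 1.18e-10, adjusted p = 0.193 with an estimated correlation). BNIP3 (0.40), KDM3A (0.37) and VEGFA (0.33) rose of the 19 hypoxia genes (adjusted p = 0.242 with an estimated correlation).

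**Figure D1:**
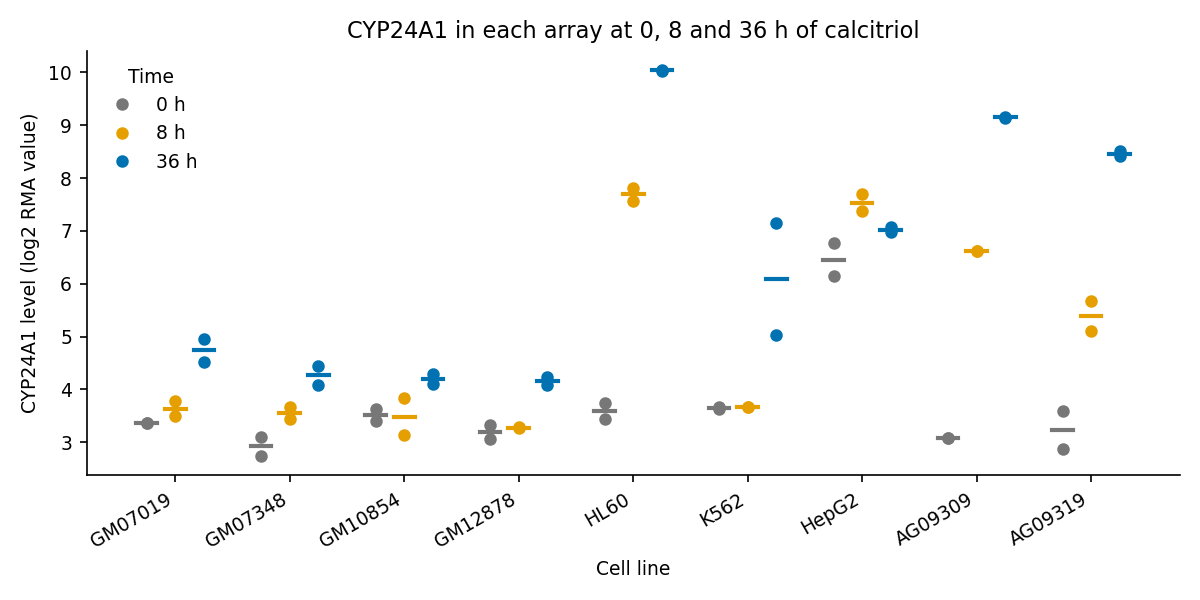
CYP24A1 level (log2 RMA value) in each array of the 9 cell lines at 0, 8 and 36 h; each point is 1 array and each bar the mean of 2. In the 2 fibroblast lines and HL60 the level rises by 5.24 to 6.44 log2 units at 36 h, HepG2 starts highest, and the 2 K562 arrays at 36 h lie apart at 7.15 and 5.03.

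The lymphoblastoid comparison asked what calcitriol did in B cell lines. At 36 h CD38, a surface ectoenzyme of activated B cells and plasma cells, rose by 2.07 ± 0.12 over the 4 lines (adjusted p = 1.09e-08), and STS, the steroid sulfatase, by 1.97 ± 0.09 (adjusted p = 7.71e-10). CAMP, which encodes the antimicrobial peptide cathelicidin, rose by 1.61 ± 0.17 (adjusted p = 4.4e-05). The B cell receptor component CD79A rose by 1.30 ± 0.11 (adjusted p = 2.31e-06) and TNFRSF17, a receptor for plasma cell survival signals, by 1.08 ± 0.10 (adjusted p = 9.81e-06). CYP24A1 rose by 1.09 ± 0.11 (adjusted p = 2.16e-05) from 0 h levels of 2.74 to 3.63, too low for an exact fold, and CLMN, TENT5C, ITM2C and ABCD2 by 1.02 to 1.16. The largest falls were smaller, led by UGT2B10, a glucuronosyltransferase (-0.55 ± 0.09, adjusted p = 0.00367), SIRPB1 (-0.46), MIR375 (-0.45) and GSTO2 (-0.40).

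At 36 h 221 probe sets changed over the 4 lines, 207 higher and 14 lower. The count was 117 without GM07019, 691 without GM07348, 73 without GM10854 and 117 without GM12878, the last being the 3 lines of the first title style. Leaving out 1 line took SIRPB1, MIR375 and GSTO2 to adjusted p-values of up to 0.297, 0.337 and 0.244, and after quantile normalization SIRPB1 had 0.0726. At 8 h 5 genes had risen, CD38 by 0.78 ± 0.12 (adjusted p = 0.0271), the peroxisomal transporter ABCD2 by 0.68 ± 0.10, CLMN by 0.65 ± 0.09, ZNF589 by 0.56 ± 0.09 and ACSL1 by 0.55 ± 0.09. After quantile normalization CD38 at 8 h was 0.80 (adjusted p = 0.0901). Without GM07019, GM07348 or GM12878 no probe set changed at 8 h by limma (0, 615 at an unadjusted p under 0.05 in all 4 lines), and 2 did without GM10854.

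Immune gene lists were among those called in the lymphoblastoid mean at 36 h. Of 20 B cell genes 6 rose, among them CD38, CD79A, the complement receptor CR2 (0.77 ± 0.11) and the costimulator CD80 (0.50 ± 0.08), and 12 when adjusted over the list alone (list adjusted p = 4.06e-11, adjusted p = 0.0405 with an estimated correlation). Of 24 NF-kB and inflammatory genes 6 rose, with the chemokines CCL4 (0.79) and CCL22 (0.74 ± 0.12) and the feedback inhibitors NFKBIA (0.62) and TNFAIP3 (0.43), and 12 when adjusted over the list alone (adjusted p = 1.32e-08, adjusted p = 0.0362 with an estimated correlation). Of 21 interferon-stimulated genes 8 rose, such as IFIH1 (0.57 ± 0.11), IFI44L (0.54 ± 0.10) and RSAD2 (0.47), and 16 when adjusted over the list alone (adjusted p = 6.69e-16, adjusted p = 0.102 with an estimated correlation). Of 13 cholesterol synthesis genes 4 rose, led by INSIG1 (0.67 ± 0.08) and HMGCS1 (0.51), and 11 when adjusted over the list alone (adjusted p = 4.4e-13, adjusted p = 0.183 with an estimated correlation). Of 29 genes at autoimmune disease loci 3 rose, the phosphatase PTPN2 (0.58), the transcription factor IRF8 (0.51) and TNFAIP3, and 9 when adjusted over the list alone (adjusted p = 0.000745, adjusted p = 0.134 with an estimated correlation). BNIP3 (0.55) and KDM3A (0.42) rose of 19 hypoxia genes (adjusted p = 0.395 with an estimated correlation), and DDIT4 (0.76) and the cystine transporter SLC7A11 (0.45) of 19 stress genes (adjusted p = 0.509 with an estimated correlation). The vitamin D response list as a whole was not called (5 of 32 members rose, 7 rose and 4 fell when adjusted over the list alone, adjusted p = 0.26).

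**Figure D2:**
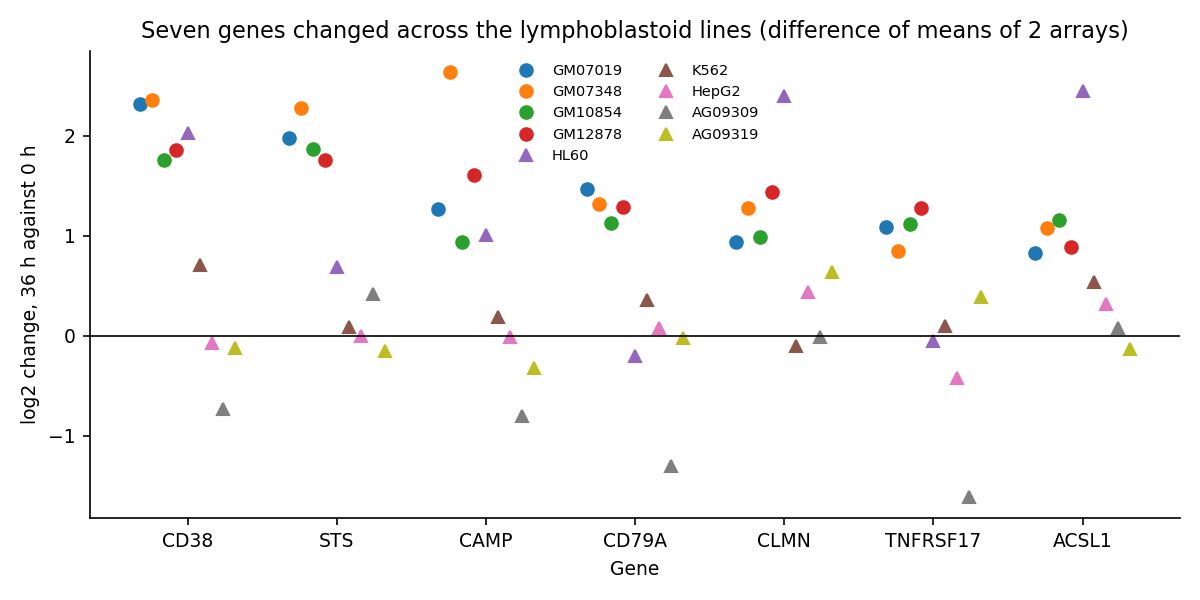
Log2 change at 36 h against 0 h of 7 genes in each line, as differences of the means of 2 arrays; circles are lymphoblastoid lines and triangles the others. CD38 lies between 1.75 and 2.35 in the 4 lymphoblastoid lines and at 2.03 in HL60, and CLMN and ACSL1 are higher in HL60, at 2.40 and 2.44, than in any lymphoblastoid line.

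Each lymphoblastoid line was also tested alone. CD38 and STS rose in all 4 lines at 36 h, CD38 by 2.31 ± 0.25 in GM07019 (adjusted p = 3.92e-07), 2.35 ± 0.25 in GM07348, 1.75 ± 0.25 in GM10854 (adjusted p = 0.000259) and 1.86 ± 0.25 in GM12878 (adjusted p = 2.44e-05), and STS by 1.76 to 2.28. CAMP rose by 1.27 ± 0.20 in GM07019, 2.64 ± 0.20 in GM07348 (adjusted p = 2.33e-11) and 1.61 ± 0.20 in GM12878, and was 0.94 ± 0.20 in GM10854 (adjusted p = 0.0527, but 0.0275 after quantile normalization, 0.0171 after centring and 0.00549 without the 3 arrays that stood apart). CD79A also rose in all 4 lines, by 1.47 ± 0.22 in GM07019, 1.32 in GM07348, 1.13 in GM10854 (adjusted p = 0.0284) and 1.28 in GM12878. TENT5C rose in GM12878 (1.76 ± 0.21) and in GM07348 (1.34 ± 0.21, with an adjusted p of up to 0.166 when 1 array was left out), and DENND6B in GM07348 (1.33 ± 0.18). GM10854 raised CD274, the checkpoint ligand PD-L1, by 1.29 ± 0.26 (adjusted p = 0.0296) and DDX60 by 1.22 ± 0.24 (adjusted p = 0.0296). Differences between lymphoblastoid lines were not tested. CYP24A1 passed in none of the 4 lines tested alone, with 1.38 in GM07019 (adjusted p = 0.219), 1.35 in GM07348, 0.68 in GM10854 and 0.97 in GM12878. Without the 3 arrays of other lines that stood apart these changes were the same, and the adjusted p fell to 0.000137 in GM07019, 0.000103 in GM07348 and 0.0225 in GM12878.

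Probe sets changed at 36 h were 10 in GM07019, 23 in GM07348, 13 in GM10854 and 10 in GM12878, all higher. GM07019 and GM07348 shared 8, where independent lists would share 0.01. Without the 3 arrays that stood apart, which belong to other lines, the counts were 24, 62, 113 and 23, and with only the arrays of each line 43, 49, 750 and 21. Leaving out any 1 of a line's own 4 arrays gave 4 or 5 in GM07019, 6 to 18 in GM07348, 1 or 2 in GM10854 and 6 or 7 in GM12878. In GM10854 CD38, CD274 and DDX60 then reached adjusted p-values of up to 0.144, 0.478 and 0.478, in GM07019 CAMP up to 0.0902. At 8 h CAMP rose in GM07348 (1.24 ± 0.20, adjusted p = 0.0068), its 1 change, which was lost when any 1 of its arrays was left out (0). In GM07019, GM10854 and GM12878 none passed limma's test at 8 h (0 each, with 708, 212 and 232 at an unadjusted p under 0.05).

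Immune lists were also called in single lines at 36 h, where differences between lines were not tested. In the interferon-stimulated list none of 21 members passed alone in any of the 4 lines, and 8 rose in GM07019, 2 in GM07348 and 12 in GM10854 when adjusted over the list alone. Its adjusted p with an estimated correlation was 0.000203 in GM07019, 0.0185 in GM07348, 0.00454 in GM10854 and 0.286 in GM12878. For the 24 NF-kB genes these were 0.000231, 0.0031, 0.0785 and 0.0388, and none passed alone. In the B cell list 2 of 20 members rose in each line, with an adjusted p of 0.00916 in GM07019, 0.216 in GM07348, 0.0926 in GM10854 and 0.0446 in GM12878 with an estimated correlation. GM12878 also had the vitamin D response list called, with CAMP as the 1 riser of 32 (adjusted p = 0.0237 with an estimated correlation), and the stress list, with none of 19 passing alone (adjusted p = 0.0342 with an estimated correlation).

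The comparison of line classes asked whether lymphoblastoid lines responded differently from the other 5. STS rose more in the lymphoblastoid lines at 36 h, by 1.77 ± 0.17 (adjusted p = 0.0012), and so did MYRF, a membrane-bound transcription factor known from myelin formation, by 0.93 ± 0.12 (adjusted p = 0.0128). MYRF was 0.70 to 0.97 in the lymphoblastoid lines and -0.24 to 0.10 in the others. These were the 2 probe sets that differed. Without GM07019, GM07348, HepG2 or GM12878 the count was 1 each time, as it was without the 3 arrays that stood apart, where MYRF was 0.87 (adjusted p = 0.124), and in the first title style alone. MYRF reached an adjusted p of up to 0.11 when 1 line was left out. At 8 h no probe set differed by limma's test (0, with 763 at an unadjusted p under 0.05), the leading one being TENT5C, an RNA-stabilising poly(A) polymerase, at 0.99 ± 0.16 (adjusted p = 0.19). No list member passed at 36 h, and of the called lists the cell cycle median was 0.55 higher (adjusted p = 2.61e-21, adjusted p = 0.417 with an estimated correlation) and the interferon median 0.45 higher (adjusted p = 0.244 with an estimated correlation). The other class includes AG09309, whose 0 h arrays held lymphoid transcripts, as described below, and whose interferon median at 36 h was -0.52, so part of the interferon difference may come from those 0 h arrays.

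HL60, a line that can mature towards monocytes, was compared with its own 0 h arrays. At 36 h CYP24A1 rose by 6.44 ± 0.34 (adjusted p = 1.36e-16), MMP8, the neutrophil collagenase, by 5.0 ± 0.26 (adjusted p = 1.36e-16) and FBP1, a gluconeogenic enzyme, by 4.96 ± 0.21 (adjusted p = 5.83e-19). CD14, the monocyte co-receptor for lipopolysaccharide, rose by 4.10 ± 0.24 (adjusted p = 2.83e-15) and the acute-phase protein ORM1 by 3.92 ± 0.31. CAMP rose by 1.0 ± 0.20 and G0S2 by 0.88 ± 0.17, while VDR (-0.23), THBD (0.16) and CDKN1A (0.13) did not pass. The progenitor receptor KIT (-1.78 ± 0.26, adjusted p = 2.36e-05), the coagulation factor F13A1 (-1.20) and the granule protein BPI (-1.16 ± 0.22, adjusted p = 0.00168) fell. At 8 h CYP24A1 was already up by 4.10 ± 0.34, FBP1 by 2.91 ± 0.21, CD14 by 2.58 ± 0.24, CLMN by 2.28 ± 0.19 and the myeloid receptor TREM1 by 2.13 ± 0.19, and PRDX2 fell by 0.79 ± 0.17.

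In HL60 10 of 32 vitamin D response genes rose at 36 h, led by CYP24A1, FBP1, CD14 and ORM1, 22 did not pass, and 12 rose when adjusted over the list alone (list adjusted p = 4.01e-22, adjusted p = 2.12e-06 with an estimated correlation). At 8 h 7 of the 32 rose (adjusted p = 9.52e-06 with an estimated correlation). Of 23 monocyte and macrophage genes 3 rose at 36 h, CD14, TREM1 (3.46 ± 0.19) and the integrin ITGAM (1.74), and 10 when adjusted over the list alone (adjusted p = 0.000165 with an estimated correlation). The same 3 genes had passed at 8 h (adjusted p = 0.0689 with an estimated correlation). Of 15 neutrophil granule and promyelocyte genes BPI fell at 36 h, 4 fell and 1 rose when adjusted over the list alone (adjusted p = 2.09e-05, adjusted p = 0.36 with an estimated correlation), with a median change of -0.31, while the median level of that list went from 8.88 to 8.11. At 8 h GADD45A (0.95 ± 0.19) rose of 17 growth arrest and p53 genes (adjusted p = 0.478 with an estimated correlation), and NFKBIA (1.32 ± 0.18) of 24 NF-kB genes (adjusted p = 0.223 with an estimated correlation).

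In HL60 46 probe sets changed at 8 h, 45 of them higher, and 169 at 36 h, 139 higher and 30 lower. Of the rises 37 were shared by both times, where independent lists would share 0.32. Simulated unchanged groups with common 0 h arrays shared 0, but unchanged groups have few calls to share, so that value says little, and part of the overlap may come from the common arrays (covariance of all changes 0.0356, simulated 0.0261). Without 0 h replicate 1 the 8 h count was 15, without 8 h replicate 1 or 2 it was 20, and PRDX2 reached an adjusted p of up to 1, with 0.0751 after quantile normalization. At 36 h it was 78 or 94 without 0 h replicate 1 or 2 and 89 or 79 without 36 h replicate 1 or 2, CAMP, G0S2, F13A1 and BPI reaching adjusted p-values of up to 0.188, 0.178, 0.228 and 0.113. The counts were 106 and 383 without the 3 arrays of other lines that stood apart. The lymphoblastoid mean and HL60 shared 30 rises at 36 h (1.48 for independent lists), among them CD38, STS, CAMP, CLMN, CYP24A1, ACSL1, CD274 and NFKBIA.

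In K562 CYP24A1 rose at 36 h by 2.44 ± 0.34 (adjusted p = 0.000264), with 7.15 and 5.03 in the 2 arrays against 3.67 and 3.63 at 0 h, and was 0.02 at 8 h (adjusted p = 0.979). DDIT4 rose by 1.54 ± 0.25 (adjusted p = 0.0037), the organic anion transporter SLCO1A2 by 1.22 ± 0.20, the interleukin receptor IL10RA by 1.12 ± 0.20 and the phosphodiesterase PDE11A by 1.04 ± 0.21. The 12 erythroid genes had a median of -0.15 with none passing and 1 falling when adjusted over the list alone (list adjusted p = 1.45e-06, 0.0116 without the arrays that stood apart, and adjusted p = 0.0402 with an estimated correlation). DDIT4 rose of 19 stress genes, 4 when adjusted over the list alone, with a list median of 0.38 (adjusted p = 9.08e-09, 0.0212 without the arrays that stood apart, and adjusted p = 0.0407 with an estimated correlation). CYP24A1 was the 1 riser of 32 vitamin D response genes (adjusted p = 0.0576 with an estimated correlation). The cell cycle list was called lower (adjusted p = 0.029, adjusted p = 0.84 with an estimated correlation) although its median was 0.015 and its mean 0.031.

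All 8 changes in K562 at 36 h were higher, and the median of all probe sets was itself 0.12 higher at 36 h. Without 36 h replicate 1, the array that stood apart, the count was 4 in the same fit, and CYP24A1 was 1.38 with adjusted p-values of up to 0.0567 when 1 array was left out. DDIT4 was then 0.83 (adjusted p up to 0.426), SLCO1A2 0.73 (0.426) and IL10RA 0.63 (0.619), and PDE11A had an adjusted p of 0.0825 after quantile normalization. With only the K562 arrays none passed limma's test (0, with 766 at an unadjusted p under 0.05). The count was 488 without 36 h replicate 2, 3 without 0 h replicate 1 and 1 without 0 h replicate 2. At 8 h none passed limma's test (0, with 941 at an unadjusted p under 0.05, but 8 without 0 h replicate 2 and 1 without 8 h replicate 1), and the lymphocyte activation marker CD69 was -1.26 (adjusted p = 0.421, 0.0231 after quantile normalization and 0.00782 without the 3 arrays that stood apart).

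HL60 and K562, both myeloid leukaemia lines, were compared directly. CYP24A1 rose more in HL60 by 4.07 ± 0.47 at 8 h (adjusted p = 2.29e-06) and by 4.0 ± 0.47 at 36 h (adjusted p = 1.51e-06). At 0 h it lay at 3.75 and 3.45 in HL60 and at 3.67 and 3.63 in K562, well below the array medians in both lines, so the fold sizes are not exact. At 36 h the difference was 4.72 ± 0.37 for MMP8, 4.63 ± 0.30 for FBP1, 3.81 ± 0.34 for CD14 (adjusted p = 1.16e-09) and 3.29 ± 0.50 for ORM2. F13A1 (-1.83), KIT (-1.64 ± 0.36), SLCO1A2 (-1.45) and the asparagine synthetase ASNS (-1.31 ± 0.25) rose less or fell more in HL60. Of 32 vitamin D response genes 3 differed at 8 h and 5 at 36 h, 8 and 7 when adjusted over the list alone (adjusted p = 0.00726 and 0.000205 with an estimated correlation). Of 23 monocyte genes 2 differed at 8 h, CD14 and TREM1 (adjusted p = 0.443 with an estimated correlation), and 3 at 36 h, CD14, TREM1 (3.26) and ITGAM (adjusted p = 0.00146 with an estimated correlation). In the stress list ASNS and PHGDH (-1.19) were lower in HL60 (adjusted p = 0.244 with an estimated correlation). At 8 h 9 probe sets differed, all higher in HL60, and at 36 h 36, 26 higher and 10 lower (36 and 4 after centring). Without HL60 0 h replicate 2 or K562 0 h replicate 2 the 8 h count was 17 or 32. At 36 h it was 18 without HL60 replicate 2, 117 without K562 replicate 2 and 23 without K562 0 h replicate 1. Without the 3 arrays that stood apart the counts were 52 and 85, with KIT at -1.21 (adjusted p = 0.11) and SLCO1A2 at -0.96 (adjusted p = 0.0733). When 1 array was left out F13A1, KIT, SLCO1A2 and ASNS reached adjusted p-values of up to 0.28, 0.384, 0.204 and 0.136, and after quantile normalization KIT had 0.0728.

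In HepG2, compared at 36 h with its own 0 h arrays, IGFBP1, a liver protein that binds insulin-like growth factors, rose by 2.32 ± 0.20 (adjusted p = 1.79e-09), complement C5 by 2.19 ± 0.25 and ASNS by 1.85 ± 0.18 (adjusted p = 1.84e-08). The replication histones H2BC14 (-2.04 ± 0.23) and H2AC4 (-1.60 ± 0.23) and the Wnt inhibitor DKK1 (-1.46 ± 0.24) fell. CYP24A1 did not pass, at 1.08 at 8 h (adjusted p = 1) and 0.57 at 36 h (adjusted p = 0.613), and its 0 h arrays, at 6.78 and 6.14, were the highest of any line at 0 h. Of 36 cell cycle genes 18 fell, among them TPX2 (-1.23 ± 0.27), the helicase subunit MCM4 (-1.22), TOP2A (-1.16) and the proliferation marker MKI67 (-1.16), and 32 when adjusted over the list alone (list adjusted p = 2.1e-43, adjusted p = 0.0201 with an estimated correlation). Of 19 unfolded protein and amino acid stress genes 10 rose, with ASNS, SLC7A11 (1.70 ± 0.29), TRIB3 (1.37 ± 0.17) and DNAJB9 (1.33 ± 0.22), and 13 when adjusted over the list alone (adjusted p = 0.000165 with an estimated correlation). Of 18 hepatocyte genes 4 rose, the fibrinogen chains FGB (1.44 ± 0.30), FGG (1.30) and FGA (0.89) and AMBP (1.01) (list adjusted p = 0.41 with an estimated correlation, and 0.153 at the preset one without the 3 arrays that stood apart).

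In HepG2 359 probe sets changed at 36 h, 204 higher and 155 lower. The count was 675 without 0 h replicate 1, 283 without 0 h replicate 2, the array that stood apart, 138 without 36 h replicate 1 and 106 without replicate 2. It was 633 without the 3 arrays that stood apart, and 19 with only the HepG2 arrays. At 8 h none passed limma's test (0, with 481 at an unadjusted p under 0.05), but 6 did without 0 h replicate 1 and 22 without 0 h replicate 2. At 8 h RHOB, a stress-responsive small GTPase, was 1.05 ± 0.22 (adjusted p = 0.46), and 1.33 without the 3 arrays that stood apart (adjusted p = 0.00112), where 58 probe sets changed.

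**Figure D3:**
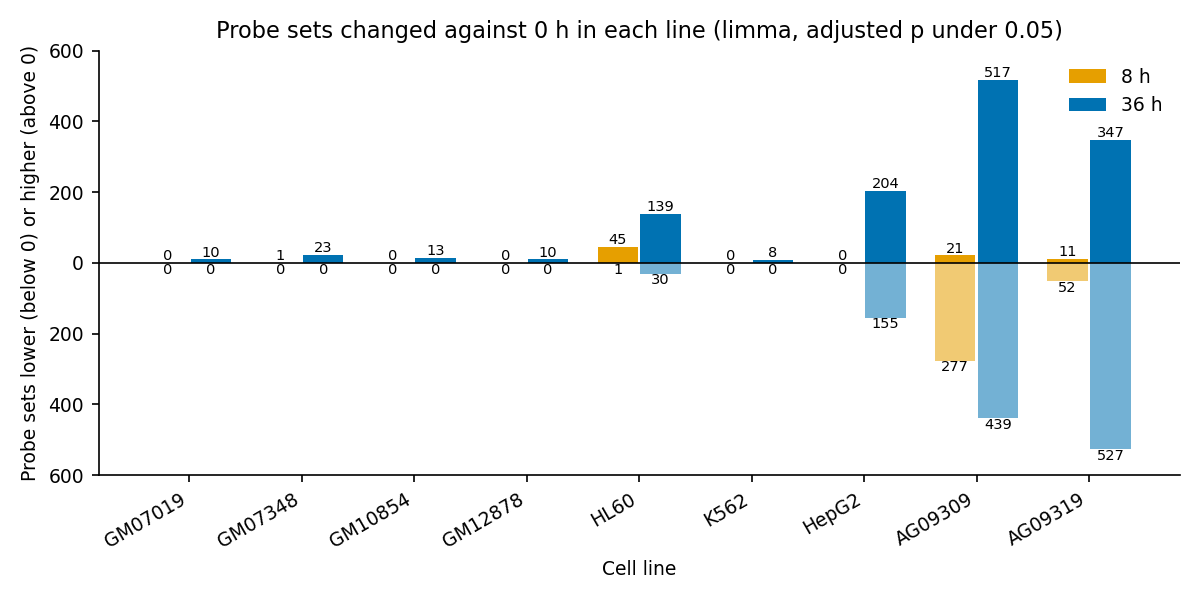
Number of probe sets higher (above 0) or lower (below 0) than at 0 h in each line at 8 h and 36 h, by limma at an adjusted p under 0.05. The 2 fibroblast lines have the most, 956 in AG09309 and 874 in AG09319 at 36 h, and every line has more at 36 h than at 8 h.

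The fibroblast line AG09319 raised CYP24A1 by 2.17 ± 0.34 at 8 h (adjusted p = 0.00109) and by 5.24 ± 0.34 at 36 h (adjusted p = 2.53e-13). Its 0 h levels, at 3.59 and 2.87, were too low for these to be exact folds. At 36 h the growth factor PDGFD rose by 2.17 ± 0.18 (adjusted p = 7.37e-10), the steroid-converting enzyme AKR1C3 by 2.17 ± 0.28, ADHFE1 by 2.04 ± 0.20 and the iron exporter SLC40A1 by 1.99 ± 0.22. The histones H3C2 (-2.48) and H2BC14 (-2.44 ± 0.23), the replication regulator DTL (-2.20 ± 0.25) and cyclin CCNE2 (-2.16 ± 0.30) fell. Of 36 cell cycle genes 35 fell, such as CDC6 (-2.13 ± 0.28) and MCM3 (-1.84 ± 0.18), and all 36 when adjusted over the list alone (list adjusted p = 1.39e-66, adjusted p = 0.00302 with an estimated correlation). Of 19 stress genes 4 rose, DDIT4 (0.85), PSAT1 (0.73), HERPUD1 (0.63) and ATF4 (0.62) (adjusted p = 0.243 with an estimated correlation). At 8 h the anticoagulant receptor THBD rose by 0.96 ± 0.21 (adjusted p = 0.0234) and, with CYP24A1, was 1 of 2 risers among 32 vitamin D response genes (adjusted p = 0.245 with an estimated correlation). SLC7A11 (-1.86 ± 0.29, adjusted p = 0.00109) and the thrombin receptors F2RL2 (-1.61 ± 0.24) and F2R (-1.54 ± 0.33) fell.

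In AG09319 874 probe sets changed at 36 h, 347 higher and 527 lower, 1448 without the 3 arrays that stood apart, 1 with only the AG09319 arrays, and between 476 and 577 when any 1 of its arrays was left out. The 8 h count was 63, 11 higher and 52 lower, and depended on single arrays: it was 10305 without 8 h replicate 1 and 5 without 8 h replicate 2, which stood apart, and 1 without 0 h replicate 1. Without the 3 arrays that stood apart it was 11, with THBD at 0.94 (adjusted p = 0.29), F2RL2 at -1.03 (adjusted p = 0.105) and F2R at -0.63 (adjusted p = 1), and SLC7A11 reached an adjusted p of up to 0.286 when 1 array was left out. The median of all probe sets was 0.10 higher at 8 h than at 0 h. HepG2 and AG09319 shared 114 falls at 36 h (4.2 for independent lists), among them MCM2, MCM3, TOP2A, MKI67, TYMS and ID1, and 12 rises (3.64), among them DPP4, HERPUD1 and PSAT1.

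AG09309, the other fibroblast line, raised CYP24A1 by 3.54 ± 0.34 at 8 h (adjusted p = 6.51e-10) and by 6.08 ± 0.34 at 36 h (adjusted p = 2.25e-16), from 3.08 in both 0 h arrays, again too low for exact folds. At 36 h the urea transporter SLC14A1 rose by 2.15 ± 0.29, SLC38A11 by 2.03 ± 0.21, the growth factor TGFB2 by 1.96 ± 0.24 and VDR by 0.91 ± 0.20 (adjusted p = 0.00311). The largest falls were in lymphoid genes that fibroblasts do not normally express, already at 8 h, among them the leukocyte actin bundler LCP1 (-5.77 ± 0.16, adjusted p = 4.23e-25), the B cell antigen MS4A1 (-4.77 ± 0.21, adjusted p = 6.73e-19), GPR15 (-5.02 ± 0.18) and CD53 (-4.14 ± 0.24). LCP1 stood at 9.54 ± 0.10 (SD, n = 2) at 0 h and at 3.77 at 8 h, too low for an exact fold, against 4.03 in AG09319 and 11.52 in GM12878 at 0 h, while the collagen gene COL1A1 was 11.63 at 0 h and 12.16 at 8 h in AG09309. The transcription factor FOS fell by 4.13 ± 0.20 at 8 h (adjusted p = 4.16e-18), from 9.87 to 5.75, against 5.2 to 5.64 in the lymphoblastoid lines at 0 h.

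Of 20 B cell genes 11 fell in AG09309 at 8 h and 13 at 36 h (adjusted p = 1.08e-05 and 0.000253 with an estimated correlation), and of 9 MHC class II genes 3 and 4 (adjusted p = 0.000508 and 0.00411 with an estimated correlation). Of 21 interferon-stimulated genes 10 fell at 8 h, such as IFI44L (-4.12) and MX1 (-2.63), and 9 at 36 h (adjusted p = 7.48e-07 and 0.000203 with an estimated correlation). Of 15 immediate early and heat shock genes 8 fell at each time, with FOSB (-3.37), EGR1 (-2.42) and JUN (-1.32) at 8 h (adjusted p = 7.15e-09 and 2.23e-07 with an estimated correlation). Of 24 NF-kB genes 4 fell at 8 h, and 9 fell and IL6 (1.03) rose at 36 h (adjusted p = 3.39e-06 and 0.000228 with an estimated correlation). Of 29 autoimmune locus genes 5 fell at 8 h (adjusted p = 0.0153 with an estimated correlation), and at 36 h 4 fell and 2 rose, IL7R (1.38) among them (adjusted p = 0.443 with an estimated correlation). Of 36 cell cycle genes 16 fell at 36 h, among them BUB1B (-1.23) and CDC6 (-1.21), and 31 when adjusted over the list alone (adjusted p = 0.134 with an estimated correlation). CYP27A1 (0.97), CYP24A1 and VDR rose of 14 receptor and metabolism genes (adjusted p = 0.198 with an estimated correlation), and PDGFRB (0.91) and COL3A1 (0.90) of 26 fibroblast and extracellular matrix genes (adjusted p = 0.731 with an estimated correlation).

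In AG09309 298 probe sets changed at 8 h, 21 higher and 277 lower, and 956 at 36 h, 517 higher and 439 lower. Of these 15 rises and 224 falls were shared by both times, where independent lists would share 0.56 and 6.26. Simulated unchanged groups, with few calls to share, shared 0, and part of the overlap may come from the common 0 h arrays and their lymphoid signal (covariance 0.0796, simulated 0.0263). Without 0 h replicate 1 the 8 h count was 180, and the 36 h count was 408 or 409 without a 0 h array and 523 or 475 without a 36 h array. The counts were 494 and 1658 without the 3 arrays of other lines that stood apart. Among the 7593 of 19436 probe sets lower in the lymphoblastoid lines than in AG09319 at 0 h, chosen after the data were seen, 18 changed at 8 h and 622 at 36 h.

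Because the lymphoid signal lay in the 0 h arrays, AG09309 was also compared between 8 h and 36 h, a comparison chosen after the data were seen. CYP24A1 rose by a further 2.54 ± 0.34 (adjusted p = 7.24e-05), SLC38A11 by 1.59, the calcium-activated channel family member ANO3 by 1.51 and the retinaldehyde dehydrogenase ALDH1A1 by 1.36. The largest fall was in CD53 (-1.36 ± 0.24, adjusted p = 0.00365), a gene of the lymphoid signal, so some of that signal still fell after 8 h. NPR3 (-1.30) and ESM1 (-1.19) also fell. The 74 probe sets changed were 57 higher and 17 lower. The cell cycle list had a median of -0.57 (adjusted p = 1.79e-20, adjusted p = 0.263 with an estimated correlation), and the B cell list one of -0.07 (adjusted p = 0.873).

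**Figure D4:**
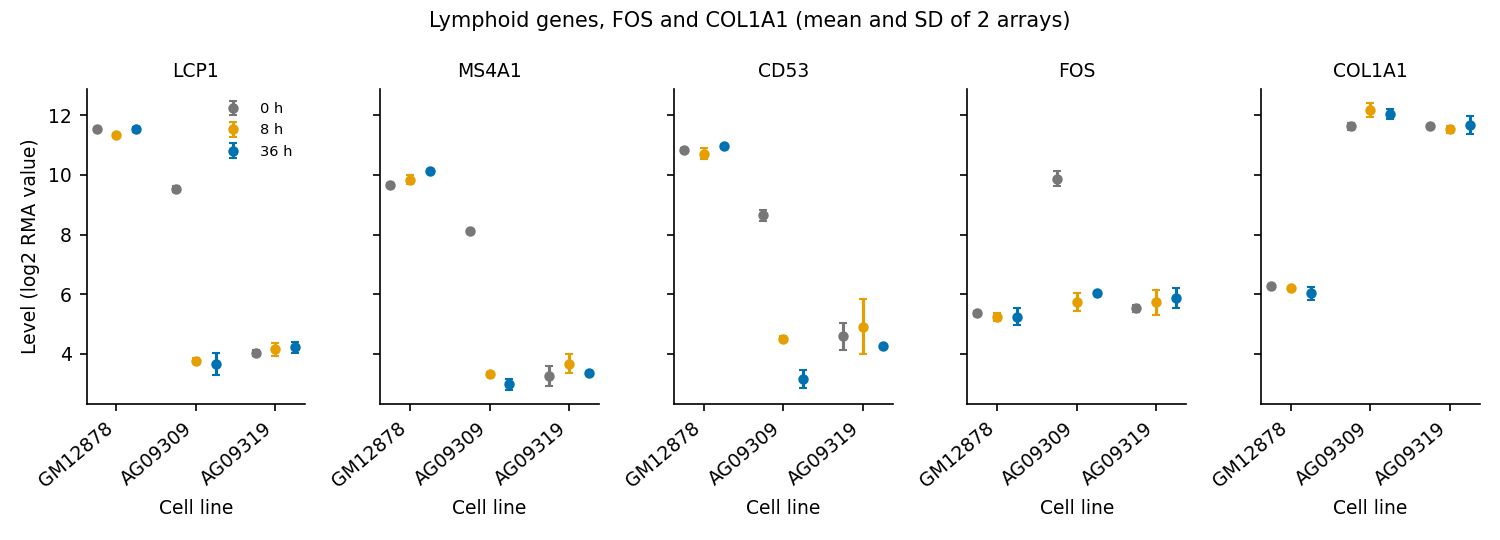
Levels (log2 RMA value, mean and SD of 2 arrays) of LCP1, MS4A1, CD53, FOS and COL1A1 at 0, 8 and 36 h in GM12878, AG09309 and AG09319. LCP1 in AG09309 is 9.54 at 0 h and 3.77 at 8 h, while COL1A1 stays above 11 in both fibroblast lines.

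The 2 fibroblast lines were compared directly. At 8 h the changes of LCP1 (-5.89 ± 0.23), MS4A1 (-5.18), GPR15 (-5.15), CD53 (-4.47) and FOS (-4.32) were lower in AG09309, and those of SLC7A14 (1.88 ± 0.29), SESN3 (1.86) and the cadherin FAT4 (1.79) higher. At 36 h the changes of the DNA-binding inhibitor ID3 (2.32 ± 0.29), the transcription factor ETV1 (2.18) and the ion channel TRPA1 (1.99) were higher in AG09309. Those of LCP1 (-6.06) and IFI44L (-4.43) were lower. ID3 was itself among the falls called in AG09319 at 36 h. Of 36 cell cycle genes 5 differed at 36 h, higher in AG09309, with MCM3 (1.15), MCM4 (1.14) and MCM7 (1.03) (adjusted p = 0.499 with an estimated correlation). The B cell list differed with 10 of 20 members lower at 8 h and 8 at 36 h (adjusted p = 0.000205 at both times with an estimated correlation). The AG09309 0 h arrays held lymphoid transcripts, as described above, so the lower changes of LCP1, MS4A1, GPR15, CD53 and the B cell list may carry that 0 h signal. The counts were 286 at 8 h, 82 higher and 204 lower, and 455 at 36 h, 216 higher and 239 lower. They were smaller among the probe sets lower in lymphoblastoid lines than in AG09319, which are also fewer to test. At 8 h the count was 5161 without AG09319 8 h replicate 1 and between 149 and 188 without AG09309 0 h replicate 1 or 2, AG09309 8 h replicate 2, AG09319 0 h replicate 1 or AG09319 8 h replicate 2. At 36 h it was 247 to 303 without AG09309 0 h replicate 1 or 2, AG09309 36 h replicate 2, AG09319 0 h replicate 1 or AG09319 36 h replicate 1, and 880 without the 3 arrays that stood apart. SESN3 and TRPA1 reached adjusted p-values of up to 0.055 and 0.123 when 1 array was left out. The lines shared 74 rises (9.23 for independent lists), among them CYP24A1, DPP4, EFL1, SERINC2, AKR1C3 and PDGFD, and 79 falls (11.9), among them CDC6 and MCM2.

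**Figure D5:**
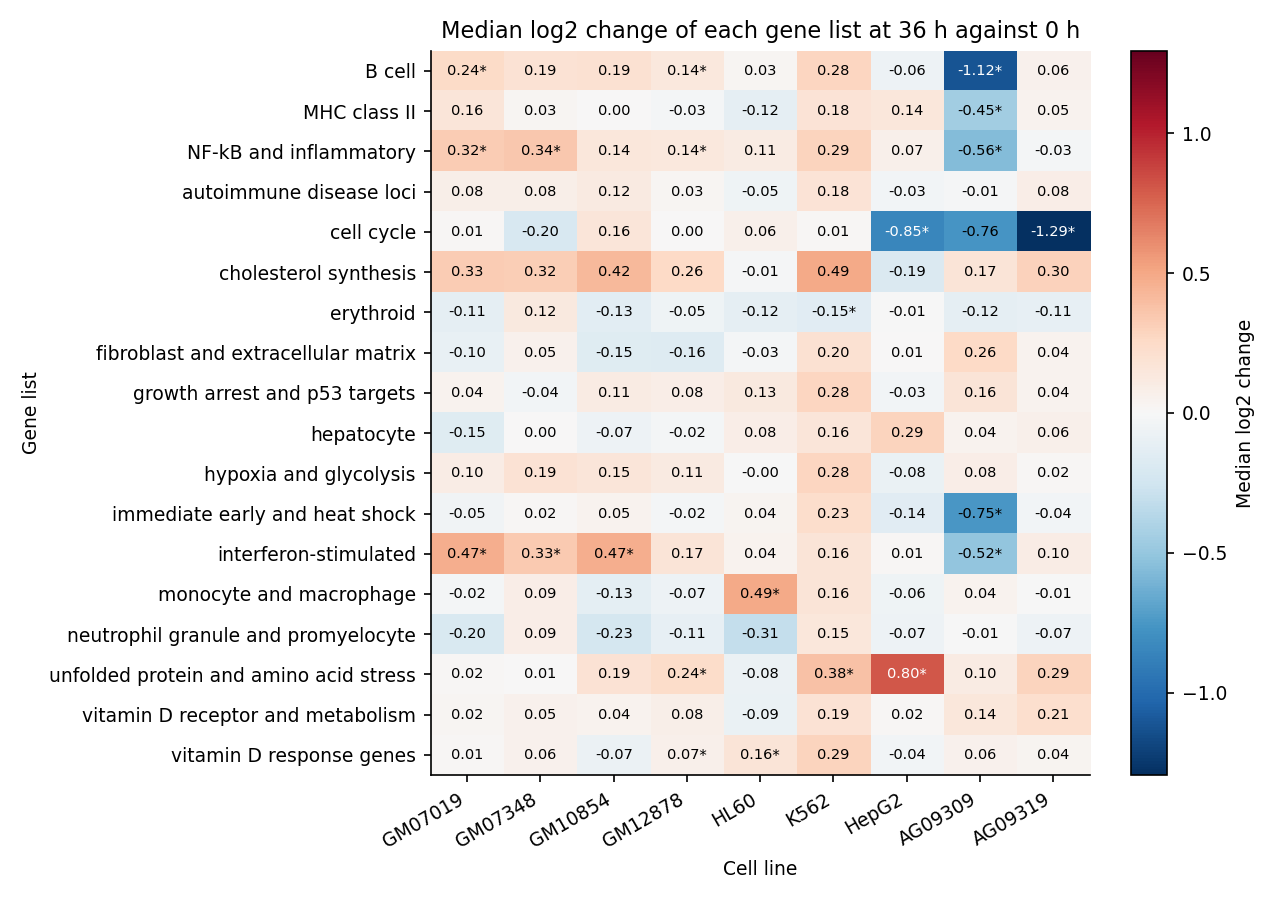
Median log2 change of the 18 gene lists at 36 h against 0 h in each line; colour and printed value give the median, and a star marks an adjusted p under 0.05 with an estimated correlation. The cell cycle list is lowest in AG09319, the stress list highest in HepG2, the monocyte list highest in HL60 and the B cell list lowest in AG09309.

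The last comparison asked whether the receptor level at 0 h went with the response over the 9 lines. VDR at 0 h was highest in HL60 (5.98) and AG09319 (5.78), and between 4.66 and 5.28 in the other lines. Its correlation with the CYP24A1 change was r = 0.73 at 8 h (two-sided exact permutation p = 0.027, Benjamini-Hochberg 0.0774 over 4 relations) and r = 0.699 at 36 h (exact p = 0.0387, Benjamini-Hochberg 0.0774). Spearman's rho was 0.633 (exact p = 0.076) and 0.55 (exact p = 0.133). With the number of changed probe sets r was 0.216 at 8 h (exact p = 0.474) and 0.372 at 36 h (exact p = 0.327), and rho 0.785 (exact p = 0.0212, Benjamini-Hochberg 0.0848) and 0.577 (exact p = 0.11). No relation passed after adjustment. The CYP24A1 changes started well below the array medians in every line but HepG2 (6.78 and 6.14), so they are not exact folds and not strictly comparable between lines. Without HL60 and AG09319, the lines farthest from the median VDR level, r was 0.379 and 0.183 for CYP24A1 at 8 h and 36 h. For the counts at 8 h and 36 h it was 0.378 and 0.272. Leaving out the most extreme VDR levels narrows their range, which can lower r by itself. The lower r for CYP24A1 therefore cannot tell whether the relation is absent among the other lines. In the 6 lines of the first title style, a subset chosen after the data were seen, r was 0.768 (exact p = 0.0181, Benjamini-Hochberg 0.0724) and 0.604 (exact p = 0.25) for CYP24A1 and 0.157 (exact p = 0.475) and 0.171 (exact p = 0.451) for the counts. The second style has 3 lines, too few for such a test. The counts also carry the lymphoid signal of the AG09309 0 h arrays (298 and 956, but 18 and 622 among the 7593 of 19436 probe sets lower in lymphoblastoid lines than in AG09319, which are also fewer to test) and the apart array of AG09319 (63 at 8 h, but 5 or 10305 without 1 of its 8 h arrays).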

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

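Among the tests of this part, the swap in AG09309, the shared signal of small RNA probe sets and the regroupings of samples were chosen before their results were seen, and all other tests of the 3 patterns after.

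Of 68 sets of values over lines tested, 6 had 1 line far from the others, where chance gives about 1 in 20 (5%). ACSL1 at 36 h was 2.443 in HL60 and -0.138 to 1.158 in the other lines. CD14 in HL60 was 2.584 at 8 h (others -0.25 to 0.348) and 4.098 at 36 h (others -0.37 to 0.286). CAMP at 8 h was 1.243 in GM07348 and -0.012 to 0.489 in the others. Between 8 h and 36 h AG09319 had SERPINB1 at 1.71 (others 0.19 to 0.862) and DDX60L at 1.906 (others -0.201 to 0.833), with an array that stood apart among the 2 at 8 h. Without the 3 such arrays the 9-line mean of DDX60L between these times was 0.51 (adjusted p = 0.106).

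Tested differences between groups were found for 2 probe sets between lymphoblastoid and other lines at 36 h. Between HL60 and K562 there were 9 at 8 h, with CYP24A1 at 4.074 and CD14 at 2.236, and 36 at 36 h, with CYP24A1 at 4.001 and CD14 at 3.812. Between AG09309 and AG09319 there were 286 at 8 h and 455 at 36 h, which include the lymphoid signal of the AG09309 0 h arrays. Among the 12083 probe sets without a name, which no comparison used, 1 was higher at 36 h over 9 lines and 2 over the lymphoblastoid lines, and 47 changed from 8 h to 36 h over 9 lines, 42 of them higher. In AG09309 35 of them changed at 8 h and 258 at 36 h, and the fibroblast lines differed in 25 and 45.

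Lymphoid transcripts were high in both AG09309 0 h arrays and low afterwards. A swap or mislabelling with a lymphoblastoid line is argued against by 26 genes abundant in AG09319 and low in lymphoblastoid lines, whose median difference between 0 h and 8 h was -0.118 (SD 0.262). A lowering of the fibroblasts' own transcripts is argued against by 34 genes that differ between lymphoblastoid lines. Across them the 0 h excess went with the profile of GM12878 (r = 0.602, permutation p = 5e-04, with genes shuffled as if independent). The other lines had -0.36 to -0.121, which is no separate evidence. Each line was set against the mean of the others, so a high value for 1 lowers the rest. RNA or cells of a lymphoblastoid line like GM12878 in the 0 h samples may account for it, with an implied share of 16.1% (quartiles 14.3 and 19.4). Of 41 genes abundant in such lines 82.9% lay over 1 log2 unit higher at 0 h, between the bounds of 75% and 90% set for deciding. A share this small need not lift the genes with the smallest gap between the lines by over 1 log2 unit, so a mixture could itself miss the upper bound. The test therefore cannot decide, and a mixture stays open. Of the 41, 100% were higher at 0 h by some amount; for these 41 and 34 genes the level limits were lowered after the first ones left 4 (100% over 1 log2 unit higher) and 3 genes, and FOS, EGR1 and JUN at 0 h lay above every lymphoblastoid line, which such a mixture alone does not give.

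Probe sets of small RNAs or of genes with several probe sets made up 44 of the 72 probe sets changed from 8 h to 36 h over 9 lines. Of the 44, 10 were small RNAs and 26 were from LINC00965. Without the 3 arrays that stood apart 75% of the 44 (33) were still called, over the bound set for arguing against those arrays. The 26 LINC00965 probe sets vary together and can carry that share. It therefore cannot decide whether those arrays account for the other calls. Whether a signal shared by these probe sets across an array contributes stays open. The median correlation of their deviations within groups was 0.499, just under the bound of 0.5, with 0.922 for LINC00965 and at most 0.136 in 1000 random sets. The LINC00965 probe sets measure 1 transcript and random sets hold no such repeats, so this comparison cannot show an array-wide signal. The other probe sets were not tested alone. An effect of calcitriol or culture time on these RNAs cannot be told apart from such a signal. The median of the 44 was higher at 36 h in 9 of 9 lines, but they were picked for their change between these times, and 69 of all 72 changes were rises. All 432 small RNA probe sets had a median of 0.014, positive in 5 lines.

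Amino acid stress genes were higher at 36 h in HepG2 (median 0.80) and K562 (0.38), but not in every line. The median was 0.29 in AG09319, 0.24 in GM12878, 0.19 in GM10854, 0.10 in AG09309, 0.02 in GM07019, 0.01 in GM07348 and -0.08 in HL60. With an estimated correlation camera called the list in GM12878 (adjusted p = 0.0342) as well as in K562 (adjusted p = 0.0407), so the rise was not particular to HepG2 and K562. In K562 DDIT4 alone of 19 members passed, at 1.54, and it was 0.83 without the array that stood apart. If the stress genes followed calcitriol through its receptor, their median could go with the CYP24A1 change. Over the 9 lines r was -0.395 (exact permutation p = 0.306, rho -0.45 with exact p = 0.23). Without the 2 lines farthest from the median r was -0.066, so the relation decides nothing. Culture time, for example medium use over 36 h, might do the same, and the median was positive in 8 of 9 lines. These cannot be told apart, because no untreated cultures of the same age were analysed here.

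Other regroupings of the samples were counted for the comparisons over lines, with each count including the real grouping. Over 9 lines 1 of 100 splits, the real one, gave as many calls at 36 h against 0 h (92, the highest other 34). The same held at 36 h against 8 h (1 of 100, 72 against 8). Chance is thus unlikely, but 100 splits cannot exclude it. The transcript LINC00965 alone makes up 26 of the calls in each. Between 8 h and 36 h each title style alone, with fewer lines, gave 0. At 8 h the real count was 0, which all 100 splits reach by construction (highest other 1), so they decide nothing. For the class difference chance cannot be excluded at 36 h, with 6 of 100 splits giving at least 2 and the highest 87. At 8 h the real count was again 0, reached by 100 of 100 by construction, and 1 split gave 1482, for which no cause was tested. The 4 lymphoblastoid lines allow 8 splits, too few for a share under 0.05, with 5 real calls against 0 in the highest other at 8 h and 221 against 12 at 36 h.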

How the results depend on the processing

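Leaving out the 3 arrays that stood apart, leaving out small RNAs and restricting AG09309 to probe sets lower in lymphoblastoid lines than in AG09319 were tests chosen after the data were seen, and the other alternatives were chosen before. Counts are of changed probe sets, a count not given under an alternative stayed within 1.5 times its value in the report, and no count or named gene reversed. Of 326 named results 309 kept their direction and side of the threshold after quantile normalization (14 no longer passed, 3 newly passed), 316 after centring (9 and 1) and 291 without the 3 arrays (27 and 8). Leaving out 1 array or line at a time ended 74 and left 252, and newly passed were 4 at their highest value and 1 at its lowest. The list tests gave 172 calls, 138 after quantile normalization, 173 after centring, 166 without the 3 arrays and 44 with an estimated correlation. With the correlation estimated, lists of genes that vary together count for less by construction. With the replicate number as a block within each line 125 list calls were made in single lines and pairs against 124. The deviations of equal numbers went together between all 3 pairs of times in K562 (0.356 to 0.585), GM07348 (0.235 to 0.343) and GM12878 (0.106 to 0.308), a hint from the data alone, and not in the other 6 lines, where they ran down to -0.414. For the changes in the counts below the cause was not tested except where stated. A filter on dim probe sets tests fewer of them.

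After quantile normalization the 36 h counts were 18 in GM07019, 37 in GM07348, 29 in GM10854, 13 in K562 and 871 in HepG2, the 8 h counts 2 in GM07348, 1 in K562 and 1 in HepG2, and HL60 and K562 differed in 17 at 8 h and 64 at 36 h. After centring GM10854 had 21 at 36 h, and HL60 and K562 differed in 18 at 8 h. Among brighter probe sets alone, which are fewer, the 36 h counts were 6 in GM07019, 7 in GM10854, 617 in AG09309 and 5 in K562, the 8 h counts 30 in HL60 and 15 in AG09319, and the class difference at 36 h was 1. With a trend and robust moderation the lymphoblastoid 8 h count was 10 and the class difference at 36 h was 0. With 1 probe set per gene the 9-line counts were 40 at 36 h and 28 between 8 h and 36 h. The main calls covered 66 and 44 genes. Counting LINC00965 once is thus not the whole difference, and other genes also lost their call. With a change of at least 0.58, a stricter threshold, they were 15 and 11, and the lymphoblastoid counts 3 at 8 h and 62 at 36 h.

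With only the arrays of the lines compared, which leaves few degrees of freedom, the 8 h counts were 8 in GM07019, 11 in GM07348 and 0 in AG09319. The 36 h counts were 43 in GM07019, 49 in GM07348, 750 in GM10854, 21 in GM12878, 0 in K562, 19 in HepG2 and 1 in AG09319. HL60 and K562 then differed in 5 at 8 h and 17 at 36 h, and the fibroblast lines in 85 and 94. With array weights the 8 h counts were 8 in GM07348, 640 in AG09309 and 0 in AG09319, and the 36 h counts 39 in GM07019, 46 in GM07348, 834 in GM10854, 25 in GM12878, 2200 in AG09309, 1 in K562 and 171 in HepG2. HL60 and K562 differed in 20 and 21, and the fibroblast lines in 90 and 886. With the replicate number as a block K562 had 1 and AG09319 115 at 8 h. With arrays fitted one by one, so that the spread is between arrays and not lines, the 9-line counts were 37 at 8 h, 981 at 36 h and 978 between the times, the lymphoblastoid 8 h count 8, and the class difference 20 at 8 h and 351 at 36 h. With the block added these were 37, 1075 and 1314, and 22 and 367 for the class difference.

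In the first title style alone, with fewer lines, the 9-line counts were 29 at 36 h and 0 between 8 h and 36 h, the lymphoblastoid counts 0 at 8 h and 117 at 36 h, and the class difference at 36 h was 1. In the second style both 9-line counts were 0. Other comparisons could not be run within the second style, which has too few lines.

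Without the 3 arrays that stood apart the 9-line count between 8 h and 36 h was 38 and the class difference at 36 h was 1. The 8 h counts were 494 in AG09309, 106 in HL60, 1 in K562, 58 in HepG2 and 11 in AG09319. The 36 h counts were 24 in GM07019, 62 in GM07348, 113 in GM10854, 23 in GM12878, 1658 in AG09309, 383 in HL60, 633 in HepG2 and 1448 in AG09319. HL60 and K562 differed in 52 and 85, and the fibroblast lines in 880 at 36 h. Without small RNAs and with 1 probe set per gene the 9-line counts were 36 at 36 h and 5 between 8 h and 36 h. Among the 7593 probe sets lower in lymphoblastoid lines than in AG09319, AG09309 had 18 at 8 h and 622 at 36 h, and the fibroblast lines differed in 71 and 227.

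Leaving out 1 line at a time gave 45 to 155 over 9 lines at 36 h, 40 to 126 between 8 h and 36 h, 0 to 2 over the lymphoblastoid lines at 8 h, 73 to 691 at 36 h, and 1 to 3 for the class difference at 36 h. Leaving out 1 array, with the lone array of its group assumed to vary like the other groups, gave at 36 h 4 to 5 in GM07019, 6 to 18 in GM07348, 1 to 2 in GM10854, 6 to 7 in GM12878, 408 to 523 in AG09309, 78 to 94 in HL60, 1 to 488 in K562, 106 to 675 in HepG2 and 476 to 577 in AG09319. At 8 h it gave 0 in GM07348 each time, 180 to 236 in AG09309, 15 to 42 in HL60, 0 to 8 in K562, 0 to 22 in HepG2 and 1 to 10305 in AG09319. The difference of HL60 and K562 was 6 to 32 at 8 h and 18 to 117 at 36 h, and that of the fibroblast lines 149 to 5161 and 247 to 394. The relations of VDR with the response had r of 0.714, 0.749, 0.248 and 0.22 after quantile normalization.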

Other observations

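The tests, genes and values of this part were chosen after the results were seen, except the levels of the fixed lists and of the fixed genes.

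Line identity showed in the marker lists. The median level of the hepatocyte list was 10.07 in HepG2 at 0 h, that of the fibroblast list 9.91 in AG09309 and 9.54 in AG09319, and that of the erythroid list 7.34 in K562. The B cell list had medians of 7.20, 7.24, 7.09 and 7.44 in GM07019, GM07348, GM10854 and GM12878 at 0 h and of 7.68, 7.60, 7.81 and 7.82 at 36 h. In AG09309 it was 5.87 at 0 h and 4.74 at 8 h. In HL60 the monocyte list went from 5.45 at 0 h to 5.82 at 8 h and 6.10 at 36 h.

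The genes higher at 36 h in each of HL60, AG09309 and AG09319 were CYP24A1, EFL1 and SERINC2. EFL1 was 1.52 in HL60, 1.35 in AG09309, 1.32 in AG09319 and -0.01 in HepG2. DPP4 was 1.94 in AG09319, 1.20 in HepG2 and 0.99 in AG09309. DDIT4 was 1.54 in K562 and -0.05 in HepG2.

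Immediate early transcripts in AG09309 at 0 h stood above the lymphoblastoid lines as well as above AG09319. EGR1 was 10.28 at 0 h and 7.87 at 8 h, against 6.27 to 6.50 in the lymphoblastoid lines and 7.56 in AG09319 at 0 h. FOSB was 8.58 and 5.21, against 4.95 to 5.51 in the lymphoblastoid lines. JUN was 8.97 and 7.64, against 5.08 to 5.38 in the lymphoblastoid lines and 7.19 in AG09319.

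Among the genes followed in every line, the monocyte marker CD14 passed in HL60 alone of the 9 lines tested one by one, and lay between -0.37 and 0.35 in the others at 8 h and 36 h. In AG09319 at 8 h it was 0.68 (adjusted p = 0.0212) without 8 h replicate 1 and -0.40 (adjusted p = 1) without replicate 2. The cell cycle inhibitor CDKN1A passed in no line at either time, with values from -0.47 in AG09319 at 8 h to 0.47 in K562 at 36 h. G0S2 passed in HL60 at 36 h was 0.68 in GM12878 at 36 h (adjusted p = 0.298), and was 0.43 in AG09319 at 8 h (adjusted p = 0.137, and 0.0219 without 8 h replicate 1). VDR passed in AG09309 at 36 h, and was 0.81 in GM07348 (adjusted p = 0.123, and 0.0212 without the 3 arrays of other lines that stood apart) and 0.56 in GM10854 (adjusted p = 0.508) at 36 h. CAMP fell in AG09309 at 36 h (-0.80 ± 0.20, adjusted p = 0.011, up to 0.178 when 1 array was left out). Of differences between lines in these genes, those of HL60 with K562 and of AG09309 with AG09319 were tested, and no others.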
